A study of Mus musculus with 16 samples.

How the data were processed

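Whole lung RNA of 16 mouse samples was measured on Affymetrix arrays, 1 array per sample. Per the labels' protocols, RNA was isolated with TRIZOL and biotin-labelled cRNA was made from 6 µg of total RNA. Per the submitters' processing notes the values were made with GCRMA, which corrects background, normalises by quantiles and summarises probes per probe set; its version is not given in the sources used here. The deposited values are intensity on a linear scale: they span 2.32 to 35181 and have no log-scale range. Log2 was taken of them and no further normalisation was applied. Titles gave the line, the exposure and the replicate number. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical. No identical columns were found, and the number of arrays per group (4) limits the precision.

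The deposited table pairs each of 45101 probe set labels with its values. In the stretches realigned below, the labels did not belong to the values beside them. Probe sets of the same gene should follow each other across arrays. Among the labels realigned below, 950 such pairs with both members above log2 6 had a median correlation of 0.112 under the labels as deposited. For the rest of the table this correlation is not given. The mismatch was noticed after the data were examined, when genes with a known high level in lung lay a fixed 64 positions from values of that kind. Labels were then realigned with a score that used no group difference: for each window of 300 labels in steps of 100, every shift was scored by how well probe sets of a gene then matched in correlation and level. A window was accepted where its best shift had a margin of over 15 log odds over the next. Each stretch of 100 labels took the shift of the accepted windows over it, gaps between stretches with the same shift were filled, and 50 labels were dropped at each end of a run. Several exploratory scans, a hidden Markov version and several acceptance rules preceded the form used, so this step was tuned on these data. It placed 15400 labels in 9 runs, of which the 3 longest held 14300. In the longest run 72 of 74 windows were over the margin; the others had the same best shift, with a lowest margin of 0.3. After realignment 1858 pairs had a median correlation of 0.404, and the correlation of levels within genes rose from 0.189 to 0.536; those values are not independent of the search. In a search on part of the genes, 1800 labels were placed. Of those that both searches placed, 0 lay on another row. For these placements 113 pairs of the genes held out had a median correlation of 0.423 against 0.15 as deposited. Realigned labels that this search did not place were not checked in this way. With genes permuted (3 times) 0 of 180 windows were accepted, against 168 with the real genes. The permuted windows did not overlap and used fewer partners per label than the real search, so these counts are not directly comparable. On rows that the search had already placed, moved by known shifts, 5200 of 12000 labels were placed, 100% of them rightly. That tests the search on its own output and cannot show that the realignment is right. All gene names here depend on this realignment, which no document of the submitters describes; whether the shift arose before or after deposit is unknown. Values at positions without a realigned label carry no gene name and were used only in the alternative over all probe sets, which needs no names.

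Symbols came from the platform annotation: of all labels 34958 had 1 symbol, 932 several, 9211 none, and 64 were controls. Of the realigned labels 14086 had 1 symbol, 392 several (not used) and 922 none. Matching gene identifiers to the RefSeq table of GRCm38.p6 changed 0 symbols; no coordinates are printed because the array annotation names no build. Genes had to exceed log2 4 on at least 4 arrays. For each gene the probe set with the highest mean over all arrays was kept, which left 7551 tested genes.

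Differences were fitted with limma 3.58.1 in R 4.3.3, with 4 group means over all 16 arrays (12 residual degrees of freedom), moderated by empirical Bayes, and adjusted by the Benjamini-Hochberg method at 0.05. The 5 comparisons were OVA against PBS in each line, the difference of those responses, and the lines against each other after each exposure. Groups, designs, filters, alternatives, gene lists and the rule for naming genes were set before the data were examined. That rule takes the 8 largest rises and 8 largest falls past the threshold per comparison, up to 4 members of each list with the smallest p, Rag1 and Rag2, and all members of a count of 5 or fewer. The transcripts shown per array beside the titles (Cd3d, Igha and Adipoq) are members of the lists and were picked after their values were seen.

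The 32 gene lists covered type 2 cytokines and receptors, alternatively activated macrophages, mucous epithelium, chemokines, eosinophils, mast cells and basophils, B cells, immunoglobulins and plasma cells, T cells, NK cells, neutrophils, macrophages and monocytes, and dendritic cells with MHC class II. They also covered interferon response, cell cycle, complement and acute phase, extracellular matrix, alveolar epithelium, club cells, ciliated cells, endothelium, cardiac muscle, skeletal muscle, adipose tissue, lymphoid follicles, erythroid cells, arginine and polyamine metabolism, eicosanoid metabolism, endoplasmic reticulum stress, immediate early genes, the circadian clock and sex-linked genes. Some genes stand in several lists (Lcn2 in neutrophil, complement and alveolar lists, Cxcl9 in chemokine and interferon lists). The 30 lists with at least 3 measured members were tested with camera at a preset correlation of 0.01 between genes; camera with an estimated correlation and fry were alternatives. The lookup of list members was corrected after results had been seen, because it had read absent genes as synonyms of others.

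Replicate numbers were checked for pairing before calls were compared. Correlations of same-number arrays' deviations from their group means were 0.30 to 0.46 between BALB/c groups, 0.32 to 0.35 between the lines after PBS and 0.19 to 0.33 after OVA, which met the rule for pairing, and 0.03 to 0.47 between the BALB-RAG groups, which did not. Arrays with the other number among 1 and 2, or among 3 and 4, correlated as well (0.33 to 0.42 between BALB/c groups), and arrays across these sets correlated negatively (−0.44 to −0.32). The main component of the deviations, with 38.4% of the variance, parted replicates 1 and 2 from 3 and 4 on all 16 arrays, and these sets were given separate runs of accessions. They were therefore treated as batches, each holding all 4 groups, and fits with a replicate block, with a batch term and within each set are given beside counts they moved by over 1.5 times.

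Alternatives were no filter and a stricter one (log2 6), all probe sets, the mean of a gene's probe sets, trended and robust variances, array weights, median centring, quantile normalisation, fits of 8 arrays alone, a 2-fold minimum, block and batch fits, and each array left out. Labels as deposited, the 3 longest runs alone, values under log2 4 set to 4, and fits without arrays whose title is in doubt were added after the data were examined. On data simulated for the 7551 genes (5 simulations, 200 genes changed) the BALB/c comparison recovered 75.4% of genes changed 2-fold and 95.8% of those changed 4-fold, with 14.4% false among those called; the BALB-RAG comparison gave 73.0%, 94.2% and 16.6%. Where the compared groups had no change, 0 to 4 genes were called per simulation for OVA in BALB/c, 0 to 2 in BALB-RAG and 0 to 9 for the lines after PBS. In the list test for BALB/c, 0 lists were called with none changed, and a raised list was called with 0 others. In all these simulations genes were drawn independently of each other, without a shift between the sets of replicates. The list test therefore cannot show how the preset correlation behaves where members of a list move together. The realignment used Python 3.11.15 with numpy 2.4.6 and numba 0.67.0, and plots matplotlib 3.10.9.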

Results

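Gene expression was measured in whole mouse lung in a model of experimental asthma. The 16 Affymetrix arrays formed 4 groups of 4: mice of the BALB/c line and of a line titled BALB-RAG, each exposed to ovalbumin (OVA), an egg protein used as an allergen, or to phosphate-buffered saline (PBS) as the control. Mice without a working Rag gene cannot rearrange antigen receptor genes and lack mature T and B cells. Tissue was taken on day 22, which was 1 day after the last exposure. Median intensity per array lay between 18.2 and 20.5, and 52.1 to 53.5% of probe sets exceeded log2 4. The number of arrays limits the precision of every comparison. Log2 4 was taken as the background: where all 4 arrays of the lower group were under it, a change is given as "at least", with values under log2 4 set to 4. Gene names rest on a realignment of probe set labels to values that left 10428 genes named, of which 7551 were tested.

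Transcripts that should report the genotype went against part of the BALB-RAG titles. Rag2 lay at the background level in every group, with log2 means of 3.05 ± 0.20 in BALB/c after PBS and 3.27 ± 0.63 in BALB-RAG after PBS (SD, n = 4), so it checked nothing, and Rag1 had no realigned probe set. The mean of the T cell list was 4.52 ± 0.15 in BALB/c after PBS and 4.57 ± 0.15 on the arrays labelled BALB-RAG after PBS (SD, n = 4). Among the arrays labelled BALB-RAG after OVA it was 5.09 on replicate 2 and 3.57, 3.78 and 3.74 on replicates 1, 3 and 4. Igha, the heavy chain of secreted IgA, read 10.79, 8.45, 9.04 and 10.72 on replicates 1 to 4 of the arrays labelled BALB-RAG after PBS, against 6.66 to 7.86 in BALB/c after PBS. After OVA it read 10.97 on replicate 2 of the arrays labelled BALB-RAG and 3.98, 3.59 and 5.52 on the others. T cell and IgA transcripts were therefore near or above BALB/c levels after PBS on 5 of the 8 arrays titled BALB-RAG. B cell transcripts were lower on the PBS arrays of that line: the B cell list read 4.69, 4.69, 5.01 and 4.58 on replicates 1 to 4, against 5.45 to 5.81 in BALB/c after PBS. Its member Ms4a1 read 4.36 to 6.17 against 6.87 to 7.48, and Ighm, the heavy chain of IgM, 7.25 to 8.75 against 8.95 to 10.15. The NK cell list read 3.66 to 4.25 on the 8 arrays labelled BALB-RAG, against 4.36 to 5.59 in BALB/c after PBS. NK cells are not among the cells named above as lacking, and the cause of this difference was not tested. Groups were kept as titled, and every direction drawn from the title is given for arrays labelled BALB-RAG.

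**Figure D1:**
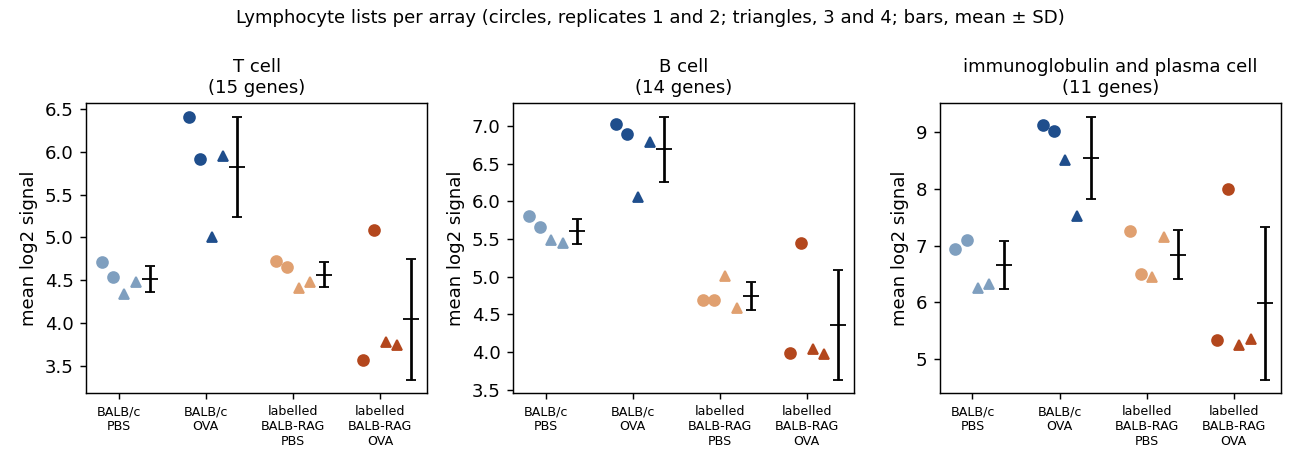
Mean log2 intensity of the T cell, B cell and immunoglobulin lists (vertical axis) on each of the 16 arrays by group (horizontal axis); points are arrays and bars are group means with SD. On the T cell list, replicate 2 of the arrays labelled BALB-RAG after OVA sits at 5.09 while the other 3 lie between 3.57 and 3.78.

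The comparison of OVA with PBS in BALB/c asked how the lung responds to the allergen. Genes of goblet cells, which secrete airway mucus, and of alternatively activated macrophages were among the largest rises. Clca1, a secreted goblet cell product, rose by log2 8.89 ± 0.92 (SE, n = 4 per group, adjusted p = 1.32e-05, limma), or 422-fold with 2 PBS arrays under log2 4 set to 4, and Chil4, a chitinase-like protein, rose 131-fold (7.04 ± 0.25). The chemokine Ccl8 rose by 6.44 ± 0.41 on the log2 scale. Rnase2a, an eosinophil-associated ribonuclease, rose at least 89.4-fold, the chemokine Cxcl9 at least 30.8-fold and Arg1, which degrades arginine, at least 21.7-fold. All 4 OVA arrays lay above all 4 PBS arrays for each of these genes. The largest falls included Pon1, a lipoprotein-associated esterase (−3.09 ± 0.28), Fabp1, a fatty acid binding protein (−2.88 ± 0.39, with 3 OVA arrays under log2 4), Cyp2e1 (−2.60 ± 0.43) and Bpifa1, a secreted airway protein (−2.35 ± 0.48). In all, 659 genes rose and 496 fell (adjusted p under 0.05).

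Of the lists, 8 kept their call in BALB/c with an estimated correlation between genes. The adjusted p-values printed for them are those of camera with the preset correlation. In the mucous epithelium list 8 of 9 members rose, 8 adjusted over the list alone, with a median of 2.61 (limma camera, adjusted p = 3.48e-11). Examples were Fcgbp (4.67 ± 0.17) and Muc5b, a gel-forming mucin (2.50 ± 0.34). In the alternatively activated macrophage list 8 of 10 rose and 1 fell, 8 and 1 adjusted over the list alone, with a median of 1.63 (adjusted p = 2.68e-09). In the dendritic cell and MHC class II list 14 of 16 rose, 14 adjusted over the list alone, with a median of 1.80 (adjusted p = 5.52e-14). Examples were the costimulatory molecule Cd86 (2.05 ± 0.13) and H2-Aa (1.34 ± 0.17). In the interferon response list 16 of 22 rose, 19 adjusted over the list alone, with a median of 1.45 (adjusted p = 2.75e-16). Examples were Iigp1 (2.42 ± 0.22) and the peptide transporter Tap1 (2.15 ± 0.20). In the cell cycle list 29 of 33 rose, 31 adjusted over the list alone, with a median of 1.69 (adjusted p = 3.58e-24). Examples were Mki67, a proliferation marker (2.59 ± 0.25), and Ccna2 (2.65 ± 0.24). In the chemokine list 12 of 20 rose, 14 up and 2 down adjusted over the list alone, with a median of 1.58 (adjusted p = 7.86e-09). Examples were Cxcl10 (2.73 ± 0.23) and the eosinophil attractant Ccl11 (2.87 ± 0.35). In the complement and acute phase list 6 of 11 rose, 8 adjusted over the list alone, with a median of 0.98 (adjusted p = 1.04e-05). Examples were C3ar1 (at least 14.4-fold) and Cfb (2.48 ± 0.34). In the list of type 2 cytokines and their receptors 2 of 6 rose, 3 adjusted over the list alone, with a median of 0.51 (adjusted p = 0.00561). They were the alarmin Il33 (1.30 ± 0.23) and Crlf2 (0.99 ± 0.21).

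A further 13 lists were called in BALB/c with the preset correlation alone. The T cell list rose with 9 of 15 members, 14 adjusted over the list alone, and a median of 1.2 (adjusted p = 9.35e-08, and adjusted p = 0.139 with an estimated correlation). Ctla4 (at least 2.18-fold) was among them. In the macrophage list 12 of 16 members rose and 1 fell, 12 and 1 adjusted over the list alone, with a median of 1.39 (adjusted p = 2.86e-06, and adjusted p = 0.135 with an estimated correlation). Itgax (2.91 ± 0.30) and the complement component C1qb (3.53 ± 0.38) were examples. In the B cell list 5 of 14 rose, 8 adjusted over the list alone, with a median of 1.2 (adjusted p = 4.29e-05, and adjusted p = 0.167 with an estimated correlation), Cd72 by 1.95 ± 0.35. In the immunoglobulin and plasma cell list 5 of 11 rose, 6 adjusted over the list alone, with a median of 0.83 (adjusted p = 0.000194, and adjusted p = 0.185 with an estimated correlation), the transcription factor Irf4 by 2.29 ± 0.20, with 3 PBS arrays under log2 4. In the extracellular matrix list 9 of 27 rose and 2 fell, 11 and 3 adjusted over the list alone, with a median of 0.58 (adjusted p = 0.000278, and adjusted p = 0.0606 with an estimated correlation). The collagen gene Col1a2 rose by 1.60 ± 0.23. Club cell genes fell, with 8 of 16 down and 1 up, 9 and 1 adjusted over the list alone, and a median of −0.67 (adjusted p = 8.91e-05, and adjusted p = 0.139 with an estimated correlation). Scgb3a2 (−0.89 ± 0.12) and Gsta3 (−1.87 ± 0.27) were examples. In the endothelium list 9 of 20 fell and 1 rose, 13 and 2 adjusted over the list alone, with a median of −0.56 (adjusted p = 3.09e-05, and adjusted p = 0.121 with an estimated correlation), the tight junction gene Cldn5 by −0.96 ± 0.15. In the cardiac muscle list 2 of 15 fell, 6 adjusted over the list alone, with a median of −1.38 (adjusted p = 0.000124, and adjusted p = 0.309 with an estimated correlation). In the immediate early list 7 of 19 fell and 2 rose, 8 and 2 adjusted over the list alone, with a median of −0.68 (adjusted p = 0.00561, and adjusted p = 0.267 with an estimated correlation). Its mean level in replicates 1 and 2 was 8.75 and 8.15 after PBS and 8.55 and 8.48 after OVA. In replicates 3 and 4 it was 9.31 and 8.53 after PBS and 8.04 and 8 after OVA. The fall of the list level thus lay in replicates 3 and 4. Klf4 (−1.32 ± 0.20) fell and Rgs1 (3.65 ± 0.49) rose.

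The other 4 lists called in BALB/c lost the call with a single array left out. In the NK cell list 3 of 10 members rose, 3 adjusted over the list alone, with a median of 0.78 (adjusted p = 0.0113, and adjusted p = 0.318 with an estimated correlation). Without BALB/c OVA replicate 4 its adjusted p was 0.0793. Its mean level in replicates 1 and 2 was 5.59 and 5.41 after PBS and 5.51 and 4.93 after OVA. In replicates 3 and 4 it was 4.48 and 4.36 after PBS and 6.22 and 6.59 after OVA. The rise of the NK list level thus lay in replicates 3 and 4. In the ciliated cell list 2 of 14 fell, 2 adjusted over the list alone, with a median of −0.27 (adjusted p = 0.0218, and adjusted p = 0.267 with an estimated correlation). In the endoplasmic reticulum stress list 4 of 22 rose, 4 adjusted over the list alone, with a median of 0.17 (adjusted p = 0.0295, and adjusted p = 0.262 with an estimated correlation). Without BALB/c PBS replicate 1 these 2 lists had an adjusted p of 0.0704 and 0.0792. The ciliated list level in replicates 3 and 4 was 6.33 and 6.14 after PBS and 6.05 and 6.36 after OVA. Its fall thus lay chiefly in replicates 1 and 2. In the lymphoid follicle list 2 of 7 rose, 4 adjusted over the list alone, with a median of 1.22 (adjusted p = 0.0317, and adjusted p = 0.262 with an estimated correlation). Without BALB/c OVA replicate 2 its adjusted p was 0.0626.

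No call was made in BALB/c for 9 lists. They were eosinophils (5 members, median 0.51, adjusted p = 0.337), neutrophils (9 members, median −0.40 but mean 0.19, adjusted p = 0.796) and alveolar epithelium (16 members, median −0.19, adjusted p = 0.26). Skeletal muscle (11 members, median −1.11, adjusted p = 0.0783), adipose tissue (11 members, median −0.37, adjusted p = 0.203) and arginine and polyamine metabolism (10 members, median 0.17, adjusted p = 0.0667) were not called either. The same held for eicosanoid metabolism (8 members, median 0.11, adjusted p = 0.262), the circadian clock (16 members, median −0.61, adjusted p = 0.128) and sex-linked genes (3 members, median 0.18, adjusted p = 0.537). Realignment placed 15400 of 45101 labels, so a list may hold only part of its genes. A missing call does not show that the cells did not change. Of the eosinophil members, Il5ra was under log2 4 on all 4 PBS arrays, and Ltc4s on 2 PBS and all 4 OVA arrays. The mast cell list had 1 measured member (Kit, −0.68 ± 0.25) and the erythroid list 2 (median −1.91), too few to test. As limits, 316 instead of 496 genes fell without BALB/c OVA replicate 2, and the count of 1155 genes became 1808 with replicate number as a block and 1874 with a batch term. Replicates 1 and 2 alone gave 1114 and replicates 3 and 4 alone 561.

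**Figure D2:**
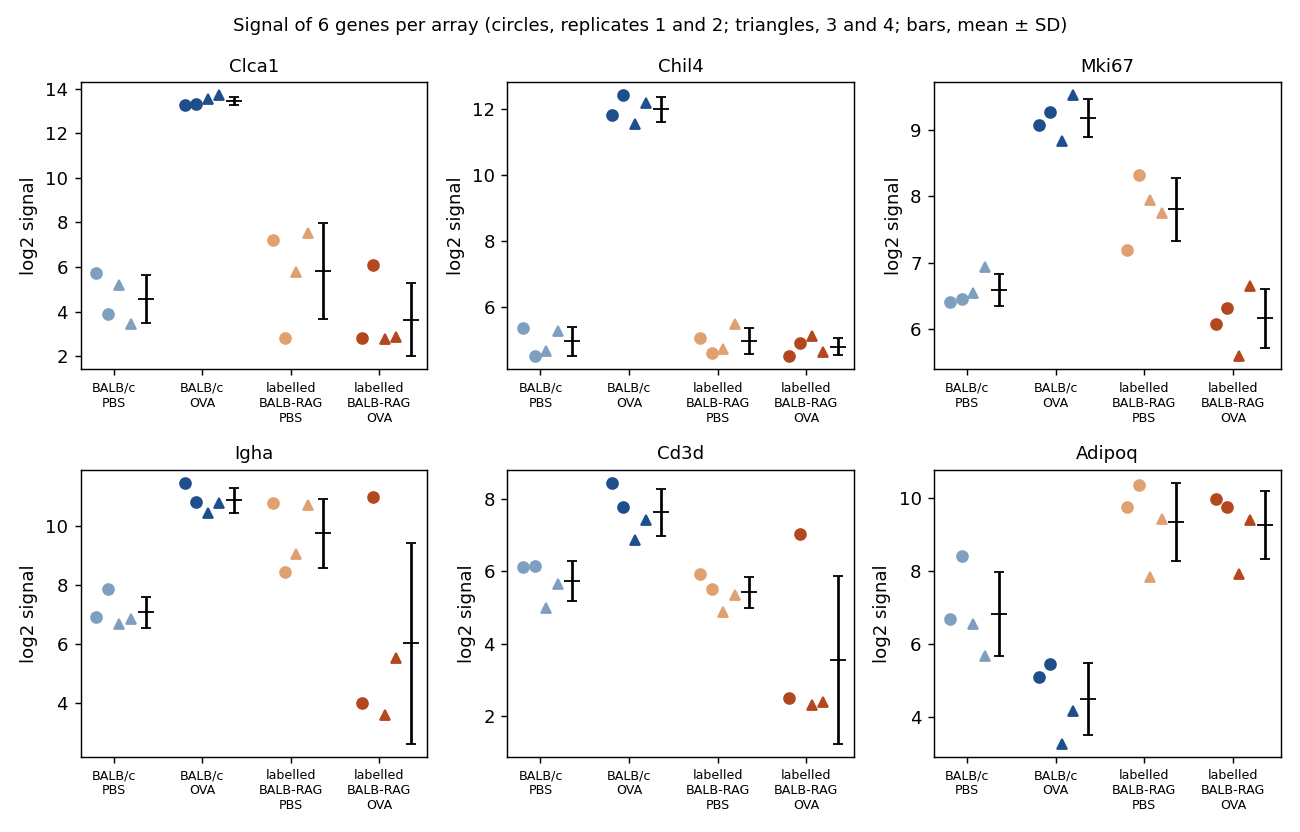
Log2 intensity (vertical axis) of Clca1, Chil4, Mki67, Igha, Cd3d and Adipoq on each of the 16 arrays by group (horizontal axis); circles are replicates 1 and 2, triangles replicates 3 and 4, and bars the group mean with SD. Chil4 has a mean of 12 in BALB/c after OVA and of 4.96, 4.96 and 4.80 in the other 3 groups.

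The same exposure on arrays labelled BALB-RAG asked how much of the response needs T and B cells, with the reservation that its PBS arrays carried lymphocyte transcripts. On these arrays 10 genes rose and 2 fell. The 8 largest rises and both falls were refitted with each array left out. Of these 10, the genes that kept the call throughout were Angptl4, an inhibitor of lipoprotein lipase (2.28 ± 0.34, SE, n = 4 per group, adjusted p = 0.0108, limma), Fam107a (2.12 ± 0.27, 0.00337), the collagen crosslinking enzyme Lox (1.55 ± 0.17, 0.000974) and Mki67, which fell (−1.64 ± 0.25, 0.011). Clca1 was not called (adjusted p = 0.56), with 3 OVA arrays and 1 PBS array under log2 4.

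In this comparison 12 lists were called, none of them with an estimated correlation. The cell cycle list fell, with 1 of 33 members past the test, 15 adjusted over the list alone, and a median of −0.67 (limma camera, adjusted p = 1.71e-23, and adjusted p = 0.0774 with an estimated correlation). The complement and acute phase list rose, with 0 of 11 members past the test, 6 adjusted over the list alone, and a median of 0.35 (adjusted p = 6.9e-07, and adjusted p = 0.0774 with an estimated correlation). Club cell genes were higher, with 0 of 16 past the test, 0 adjusted over the list alone, and a median of 0.38 (adjusted p = 0.000329, and adjusted p = 0.361 with an estimated correlation). T cell genes were lower, with 0 of 15 past the test, 0 adjusted over the list alone, and a median of −0.43 (adjusted p = 0.000289, and adjusted p = 0.469 with an estimated correlation). All 4 PBS arrays in that difference carried lymphocyte transcripts.

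The other 8 list calls on these arrays, with 0 members past the test in each, were lost when 1 array was left out. Neutrophil genes had a median of 1.09 (adjusted p = 0.00244, and adjusted p = 0.469 with an estimated correlation), with 3 of 9 up adjusted over the list alone. Macrophage genes had a median of 0.40 (adjusted p = 0.00707, and adjusted p = 0.469 with an estimated correlation), with 1 of 16 up adjusted over the list alone. Without PBS replicate 4 these had an adjusted p of 0.129 and 0.0639. The neutrophil list level in replicates 1 and 2 was 5.88 and 8.14 after PBS and 7.29 and 6.9 after OVA. In replicates 3 and 4 it was 5.8 and 5.4 after PBS and 7.44 and 6.98 after OVA. The neutrophil rise thus lay chiefly in replicates 3 and 4. Immunoglobulins had a median of −0.14 (adjusted p = 0.0186, and adjusted p = 0.479 with an estimated correlation), and 0.0677 without PBS replicate 1. The clock had a median of 0.25 (adjusted p = 0.0356, and adjusted p = 0.209 with an estimated correlation), and 0.145 without PBS replicate 2. Alveolar epithelium (median 0.12) and adipose tissue (−0.23) had adjusted p = 0.0447 each, and adjusted p = 0.469 and 0.565 with an estimated correlation. B cells (−0.21) and eicosanoid metabolism (−0.26) had adjusted p = 0.0447 each as well, and adjusted p = 0.565 and 0.229 with an estimated correlation. The call was lost for alveolar epithelium without PBS replicate 2 (0.235) and for adipose tissue without OVA replicate 3 (0.503). It was lost without PBS replicate 3 for B cells (0.352) and eicosanoid metabolism (0.174). The number of called lists was 6 without PBS replicate 4 and 7 without OVA replicate 4, and 8 of the 12 calls were kept with the replicate block. The count of 12 genes was 6 without PBS replicate 1 or OVA replicate 4, 7 without OVA replicate 1 or 3, and 19 without PBS replicate 3 (9 up, 10 down). It was 41 without OVA replicate 2, which like all 4 PBS arrays carried lymphocyte transcripts, with 18 up and 23 down, so the balance of rises and falls turned. It was 25 without BALB/c OVA replicate 3. With the replicate block it was 43, with a batch term 70, with values under log2 4 set to 4 it was 21, within replicates 1 and 2 it was 3 and within replicates 3 and 4 it was 5.

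The difference between the OVA responses was tested directly. Mucous, alternatively activated macrophage and proliferation genes responded more strongly in BALB/c. The response of Clca1 was larger there by 11.08 ± 1.30 (SE, n = 4 per group, adjusted p = 8.87e-05, limma), of Igha by 7.55 ± 1.63, of Chil4 by 7.20 ± 0.35 and of Mki67 by 4.23 ± 0.35 log2 units. Clca1 and Igha had 3 and 2 arrays under log2 4 among those labelled BALB-RAG after OVA, and with such values set to 4 the differences were 10.32 and 7.44. Part of some differences lies on the arrays labelled BALB-RAG, where Mki67 fell by −1.64 and Igha, not called there (adjusted p = 0.307), differed by −3.74 from PBS arrays that carried lymphocyte transcripts. Cyp2e1 (−3.74 ± 0.60), Pon1 (−3.49 ± 0.40), Pdk4, a brake on glucose oxidation (−3.40 ± 0.46), and Angptl4 (−3.32 ± 0.48) differed the other way. Altogether the response was more positive in BALB/c for 349 genes and more negative for 288. Of the 637, all had the same sign within both sets of replicates.

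With an estimated correlation the response differed for 5 lists, all with the more positive response in BALB/c. Their adjusted p-values are printed for the preset correlation. In the cell cycle list 28 of 33 members passed, 32 adjusted over the list alone, with a median of 2.57 (limma camera, adjusted p = 7.07e-34). In the interferon response list 11 of 22 passed, 17 adjusted over the list alone, with a median of 1.56 (adjusted p = 2.45e-16). In the mucous epithelium list 8 of 9 passed, 9 adjusted over the list alone, with a median of 2.53 (adjusted p = 9.55e-13). In the dendritic cell list 11 of 16 passed, 14 adjusted over the list alone, with a median of 1.58 (adjusted p = 5.07e-11). In the alternatively activated macrophage list 5 of 10 were up and 1 down, 7 and 1 adjusted over the list alone, with a median of 1.62 (adjusted p = 1.2e-07). Further calls were made with the preset correlation alone. In the T cell list 7 of 15 were up, 14 adjusted over the list alone, with a median of 1.85 (adjusted p = 1.19e-09, and adjusted p = 0.0988 with an estimated correlation). In the club cell list 7 of 16 were down, 10 adjusted over the list alone, with a median of −0.92 (adjusted p = 9.74e-07, and adjusted p = 0.0944 with an estimated correlation). In the chemokine list 6 of 20 were up and 1 down, 11 and 1 adjusted over the list alone, with a median of 1.14 (adjusted p = 1.64e-06, and adjusted p = 0.0988 with an estimated correlation). In the extracellular matrix list 11 of 27 were up and 4 down, 13 and 4 adjusted over the list alone, with a median of 0.94 (adjusted p = 0.000148, and adjusted p = 0.0673 with an estimated correlation). The response of Col1a1 was larger by 2.78 ± 0.41. The other 10 calls are given with the results that differ between groups.

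Across all 7551 genes the responses of the lines had a Pearson correlation of −0.096 (jackknife SE over arrays 0.087) and a Spearman correlation of −0.074. The Pearson value was close in size to its SE, so opposed responses cannot be read from it. Across the 1155 genes changed in BALB/c these were −0.164 and −0.136, with a slope of −0.053. Genes are not independent replicates. The PBS arrays labelled BALB-RAG, which enter that line's response, carried lymphocyte transcripts. Their cell cycle list level was 5.64, against 4.96 in BALB/c after PBS. As limits, the count of 637 genes was 422 without BALB/c OVA replicate 2, 1188 with the replicate block and 1255 with a batch term. It was 628 in replicates 1 and 2 and 200 in replicates 3 and 4. The 288 genes with the more negative response in BALB/c were 179, 169 and 188 without BALB/c OVA replicate 1, BALB/c OVA replicate 2 and BALB-RAG OVA replicate 4, and without BALB-RAG PBS replicate 4 both directions held 307.

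The lines were compared after PBS to see how they differ without allergen. On the arrays labelled BALB-RAG, Dbp, a clock output gene, was higher by 3.74 ± 0.56 (SE, n = 4 per group, adjusted p = 0.00163, limma), Tmem87a by 4.04 ± 0.24 and the myosin light chain Myl3 by 4.63 ± 0.92. For Dbp and Tmem87a 2 and 3 BALB/c PBS arrays were under log2 4. Nr1d1 was at least 5.27-fold higher, Ucp1 of brown fat at least 9.63-fold and the transcript BC018473 at least 6.36-fold. The chaperones Hspa1b (−3.33 ± 0.44) and Hsph1 (−2.23 ± 0.26), the matrix protease Mmp3 (−2.58 ± 0.24), Disp2 (−2.72 ± 0.26, with 3 arrays labelled BALB-RAG under log2 4) and Fos (−2.45 ± 0.46) were lower. In all, 150 genes were higher and 146 lower.

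Of the 12 lists called after PBS none kept the call with an estimated correlation. Cell cycle genes were higher for 6 of 33 members, 11 adjusted over the list alone, with a median of 0.55 (limma camera, adjusted p = 1.4e-11, and adjusted p = 0.176 with an estimated correlation), Rrm2 by 1.43 ± 0.29. Cardiac muscle genes were higher for 5 of 15, 12 adjusted over the list alone, with a median of 1.78 (adjusted p = 1.95e-11, and adjusted p = 0.231 with an estimated correlation). Adipose tissue genes were higher for 6 of 11, 8 adjusted over the list alone, with a median of 1.75 (adjusted p = 2.16e-08, and adjusted p = 0.176 with an estimated correlation). On these 2 lists BALB-RAG replicate 3 read 7.57 and 7.41, in the BALB/c ranges of 7.01 to 7.96 and 6.70 to 7.59, while the other 3 read 9.18 to 10.46 and 9.17 to 9.69. Immediate early genes were lower for 9 of 19, 14 down and 1 up adjusted over the list alone, with a median of −1.18 (adjusted p = 1.4e-11, and adjusted p = 0.143 with an estimated correlation). Klf4 (−1.33 ± 0.20) and Maff (−1.81 ± 0.30) were examples. NK cell genes were lower for 2 of 10, 6 adjusted over the list alone, with a median of −1.21 (adjusted p = 4.71e-05, and adjusted p = 0.241 with an estimated correlation). B cell genes were lower for 1 of 14, 3 adjusted over the list alone, with a median of −0.77 (adjusted p = 4.71e-05, and adjusted p = 0.241 with an estimated correlation). Interferon response genes were lower for 1 of 22, 3 adjusted over the list alone, with a median of −0.45 (adjusted p = 9.55e-05, and adjusted p = 0.288 with an estimated correlation). Endoplasmic reticulum stress genes were lower for 1 of 22, 7 adjusted over the list alone, with a median of −0.28 (adjusted p = 0.000167, and adjusted p = 0.176 with an estimated correlation). Dendritic cell genes were lower for 1 of 16, 3 adjusted over the list alone, with a median of −0.37 (adjusted p = 0.000301, and adjusted p = 0.241 with an estimated correlation). The type 2 cytokine list was lower with 0 of 6 past the test, 0 adjusted over the list alone, and a median of −0.42 (adjusted p = 0.0134, and adjusted p = 0.176 with an estimated correlation). The chemokine list, with a median of −0.35 (adjusted p = 0.0339, and adjusted p = 0.517 with an estimated correlation), lost its call without BALB-RAG PBS replicate 4 (0.212). Of its members 2 of 20 were lower, 3 adjusted over the list alone. The arginine metabolism list, with a median of −0.16 (adjusted p = 0.0455, and adjusted p = 0.288 with an estimated correlation), lost its call without BALB/c PBS replicate 2 (0.125). Of its members 2 of 10 were lower, 2 adjusted over the list alone. No call was made for T cells (median 0.02, adjusted p = 0.782) or immunoglobulins (median −0.01, adjusted p = 0.996). The count of 296 genes was 178 without BALB-RAG PBS replicate 1, 195 without BALB/c PBS replicate 1 and 194 without BALB/c PBS replicate 2. The balance of 150 higher and 146 lower was not stable: without BALB-RAG PBS replicates 1, 2, 3 and 4 in turn it was 94 and 84, 90 and 121, 276 and 135, and 87 and 131. Without BALB/c PBS replicates 1, 2 and 4 it was 106 and 89, 91 and 103, and 96 and 113. The count was 617 with the replicate block, 652 with a batch term, 258 within replicates 1 and 2 and 52 within replicates 3 and 4.

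**Figure D3:**
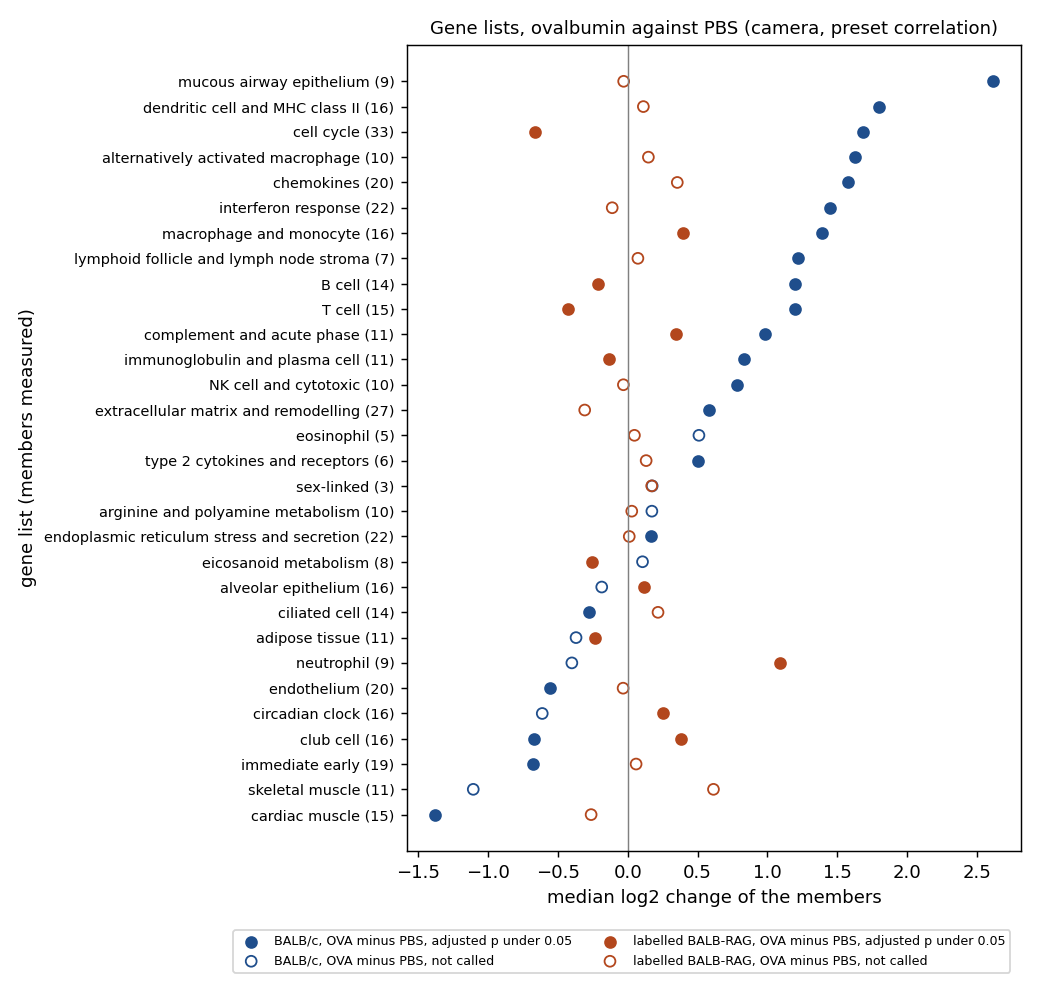
Median log2 difference between OVA and PBS (horizontal axis) for the 30 gene lists that were tested (vertical axis, with members measured), in BALB/c and on arrays labelled BALB-RAG, filled where camera with the preset correlation called the list and open where not. The cell cycle list lies at 1.69 in BALB/c and at −0.67 on arrays labelled BALB-RAG.

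After OVA the lines differed most. On the arrays labelled BALB-RAG, Clca1 was lower by −9.81 ± 0.92 (SE, n = 4 per group, adjusted p = 3.05e-06, limma), Chil4 by −7.20 ± 0.25, Ighm by −6.75 ± 0.95 and the B cell gene Ms4a1 by −4.97 ± 0.65 on the log2 scale. With the 3 arrays labelled BALB-RAG that were under log2 4 set to 4, Clca1 and Ms4a1 differed by −8.93 and −3.81. Cyp2e1 (4.94 ± 0.43), Adipoq, a fat cell hormone (4.75 ± 0.65), and Tmem87a (4.05 ± 0.24, with 3 BALB/c arrays under log2 4) were higher, and BC018473 was at least 19.9-fold higher. In all, 871 genes were higher and 906 lower. Of the genes called between the lines after PBS and after OVA, which share no arrays, 83 were higher and 71 lower in both, against 17.3 and 17.5 for independent lists, while 18 were higher after PBS and lower after OVA and 9 the reverse.

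With an estimated correlation 10 of 21 list calls after OVA held, and 9 of these lists were lower on the arrays labelled BALB-RAG. The adjusted p-values printed for these 10 are those with the preset correlation. Interferon response genes were lower for 20 of 22 members, 21 adjusted over the list alone, with a median of −2.02 (limma camera, adjusted p = 2.27e-19). Cell cycle genes were lower for 30 of 33, 31 adjusted over the list alone, with a median of −1.87 (adjusted p = 4.43e-20). Dendritic cell genes were lower for 15 of 16, 16 adjusted over the list alone, with a median of −1.90 (adjusted p = 1.86e-14). Mucous epithelium genes were lower for 8 of 9, 9 adjusted over the list alone, with a median of −2.06 (adjusted p = 1.98e-09). B cell genes were lower for 11 of 14, 12 adjusted over the list alone, with a median of −2.28 (adjusted p = 2.1e-09). Chemokines were lower for 14 of 20 and higher for 1, 15 and 1 adjusted over the list alone, with a median of −1.51 (adjusted p = 1.54e-08). Alternatively activated macrophage genes were lower for 7 of 10 and higher for 1, 7 and 1 adjusted over the list alone, with a median of −1.80 (adjusted p = 1.98e-07). Endoplasmic reticulum stress genes were lower for 11 of 22 and higher for 1, 13 and 2 adjusted over the list alone, with a median of −0.44 (adjusted p = 2.18e-05). Type 2 cytokine genes were lower for 3 of 6, 5 adjusted over the list alone, with a median of −0.58 (adjusted p = 0.00207). The circadian clock list was higher, with 8 of 16 up and 3 down, 9 and 3 adjusted over the list alone, and a median of 0.91 (adjusted p = 0.00803). Hlf, a clock output gene, was higher by 2.48 ± 0.25.

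The other 11 lists differed after OVA with the preset correlation alone. T cell genes were lower for 13 of 15, 14 adjusted over the list alone, with a median of −1.84 (limma camera, adjusted p = 4.38e-09, and adjusted p = 0.107 with an estimated correlation). NK cell genes were lower for 8 of 10, 8 adjusted over the list alone, with a median of −2.16 (adjusted p = 6.26e-06, and adjusted p = 0.115 with an estimated correlation). Immunoglobulin genes were lower for 5 of 11, 7 adjusted over the list alone, with a median of −1.04 (adjusted p = 3.8e-05, and adjusted p = 0.117 with an estimated correlation). Macrophage genes were lower for 10 of 16 and higher for 2, 10 and 2 adjusted over the list alone, with a median of −1.35 (adjusted p = 0.000141, and adjusted p = 0.163 with an estimated correlation). Extracellular matrix genes were lower for 13 of 27 and higher for 5, 14 and 5 adjusted over the list alone, with a median of −0.69 (adjusted p = 0.00372, and adjusted p = 0.107 with an estimated correlation). Arginine metabolism genes were lower for 4 of 10, 4 adjusted over the list alone, with a median of −0.59 (adjusted p = 0.00475, and adjusted p = 0.107 with an estimated correlation). Cardiac muscle genes were higher for 13 of 15, 15 adjusted over the list alone, with a median of 3.09 (adjusted p = 7.95e-10, and adjusted p = 0.117 with an estimated correlation). Club cell genes were higher for 8 of 16 and lower for 1, 12 and 2 adjusted over the list alone, with a median of 0.77 (adjusted p = 4.11e-05, and adjusted p = 0.107 with an estimated correlation). Adipose tissue genes were higher for 6 of 11, 9 adjusted over the list alone, with a median of 1.87 (adjusted p = 0.000195, and adjusted p = 0.177 with an estimated correlation). Skeletal muscle genes were higher for 2 of 11, 2 adjusted over the list alone, with a median of 2.37 (adjusted p = 0.00803, and adjusted p = 0.434 with an estimated correlation). The list level was 8.22 and 8.11 on replicates 1 and 4 of the arrays labelled BALB-RAG and 4.45 and 3.92 on replicates 2 and 3, against 3.61 to 3.90 in BALB/c, so the difference rests on 2 arrays. Endothelium genes were higher for 7 of 20 and lower for 3, 10 and 3 adjusted over the list alone, with a median of 0.35 (adjusted p = 0.0203, and adjusted p = 0.308 with an estimated correlation). Without BALB/c OVA replicate 2 the endothelium call was lost (0.0831). As limits, the count of 1777 genes was 2041 within replicates 1 and 2 and 710 within replicates 3 and 4. The titles of the arrays labelled BALB-RAG carry the reservation given above.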

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

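Apart from the tests of the difference between responses and the search for outlying arrays, all tests in this part were chosen only after the results were seen. Those of mixed RNA replaced earlier ones that were void or had not decided. An array was taken as outlying where its gap to the nearest array was larger, relative to its group's range, than Dixon's critical value for 4 samples. This held in 14 of 124 groups of 4 arrays, against about 6.2 by chance.

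Among arrays labelled BALB-RAG after OVA, lymphocyte transcripts made replicate 2 outlying on the B cell (5.45), immunoglobulin (8.0) and T cell (5.09) lists and it was low on alveolar epithelium (10.47), while the 4 PBS arrays had T cell levels like those of BALB/c but lower B cell levels (4.58 to 5.01 against 5.45 to 5.81). A swap with BALB/c arrays of the series is argued against by 75 genes outside the lymphocyte lists that part all 8 arrays of one title from all 8 of the other with means at least 1 log2 unit apart (chance would part 0.0155% of genes, and 6 met a stricter criterion used before, a gap of 1 log2 unit). RNA of BALB/c after OVA mixed into the PBS arrays is argued against for T cell genes, since none of the 8 genes with the largest OVA rises allows over 1.7% of it while the T cell list needs 18.6 to 30.4% (lower 95% limits 7.2 to 20.5%), although 90 genes that rose at least 4-fold allow medians of up to 15.7%. RNA of BALB/c after PBS is argued against for Igha, which lay at least 0.59 above every BALB/c PBS array (n = 4, exact 2-sided permutation p = 0.029, the smallest it can give). For T cell genes on replicates 1, 2 and 4 the T cell list needs 82.0 to 119.9% of it (lower 95% limits 61.8, 56.7 and 41.0%). Genes that other arrays show higher in the line labelled BALB-RAG allow medians of 8.6, 16.7 and −2.9% (upper limits 45.3, 37.3 and 20.6%). They were not cleared of heart and fat genes, which were high on those arrays, so their share may follow heart and fat content. Genes that other arrays show lower in that line allow medians of up to 43.8, 52.6 and 76.7% (upper limits 49.8, 58.3 and 83%). On replicate 1 that limit is below the T cell limit, which argues against such mixing. On replicates 2 and 4 mixing cannot be told apart. On replicate 3, low in heart and fat genes, the genes higher in the line labelled BALB-RAG allow 82.9% and this cannot be told apart, although Tmem87a read 7.72 there and 7.90 to 8.29 after OVA. A line that makes some lymphocytes, a wrong genotype within the line, lymphoid tissue taken with the lung, or an error outside the series stay open, with no group that tests them.

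Among clock genes after PBS, the 9 genes that peak with Dbp were higher by a median of 1.39 and the 5 that peak with Arntl lower (−2.09) on arrays labelled BALB-RAG, a difference of 3.48. The sets of replicates as batches do not account for this, since it was 3.24 and 3.92 within them. After OVA the difference was 1.73 over all arrays, but 3.6 within replicates 1 and 2 and 0.15 within replicates 3 and 4, so there it depended on the set. Harvest at another time of day may account for the difference after PBS, though line and time would be confounded, and after OVA it cannot be told apart, since the arms moved in opposite directions in 1 set alone. A line difference in the clock itself stays open and untested.

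Cardiac muscle and adipose genes varied between groups and arrays. Replicate 3 of the arrays labelled BALB-RAG after OVA was outlying and low on both the cardiac muscle (7.83) and adipose (7.50) lists. On the arrays labelled BALB-RAG after PBS, replicate 3 was in the BALB/c PBS range on both (7.57 and 7.41). Varying amounts of heart and fat taken with the lung are a candidate explanation, since 100% of cardiac genes and 81.8% of adipose genes deviated together within groups, against 31.2, 37.5 and 45.0% for alveolar, club cell and endothelial genes. Dilution of lung cells by infiltrating cells in BALB/c after OVA is argued against as the only cause of the cardiac fall. Cardiac genes changed by −0.81 relative to endothelial genes (SD 0.25 and 0.36, n = 4, exact 2-sided permutation p = 0.029, the smallest it can give). Dilution beside a varying heart content is not excluded. The adipose list went from 7.08 to 6.63 and the endothelial list from 8.83 to 8.36, a fall of like size, so for adipose genes dilution stays open. Why dissection would differ by line stays open, as does a line difference in these tissues.

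Other outlying arrays were BALB-RAG PBS replicate 2 on the eosinophil list (6.64) and replicate 4 on the cell cycle list (5.77), and BALB-RAG OVA replicate 3 on the NK cell list (4.25). On the skeletal muscle list BALB/c PBS replicate 1 (8.34), BALB/c OVA replicate 4 (3.90) and BALB-RAG PBS replicate 2 (8.96) were outlying. For Rag2, at background, BALB-RAG PBS replicate 1 (4.20) and OVA replicate 1 (2.92) were.

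The OVA response differed between the lines for 637 genes. The list medians of that difference (BALB/c minus BALB-RAG) were 1.62 for alternatively activated macrophages, 2.53 for mucous epithelium, 1.14 for chemokines, 1.85 for T cells, 1.58 for dendritic cells, 1.56 for interferon response, 2.57 for the cell cycle, 0.94 for extracellular matrix and −0.92 for club cells. For the 10 lists not given before, B cells had a median of 1.39 (2 of 14 up, 9 adjusted over the list alone, limma camera, adjusted p = 1.04e-05, and adjusted p = 0.143 with an estimated correlation) and immunoglobulins 0.97 (4 of 11 up, 6 adjusted over the list alone, 3.11e-05, and adjusted p = 0.143 with an estimated correlation). Macrophages had 1.03 (7 of 16 up and 1 down, 8 and 3 adjusted over the list alone, 0.00222, and adjusted p = 0.284 with an estimated correlation). Endothelium had −0.52 (5 of 20 down and 1 up, 10 and 1 adjusted over the list alone, 0.00151, and adjusted p = 0.198 with an estimated correlation). Immediate early genes had −0.94 (6 of 19 down and 1 up, 9 and 2 adjusted over the list alone, 0.00416, and adjusted p = 0.284 with an estimated correlation). In BALB/c the level of that list fell with OVA in replicates 3 and 4 alone. Ciliated cells had −0.54 (1 of 14 down, 2 adjusted over the list alone, 0.00576, and adjusted p = 0.218 with an estimated correlation). In BALB/c the ciliated list level fell with OVA chiefly in replicates 1 and 2.

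For the remaining 4 of those lists the call was lost with 1 array left out. Cardiac muscle had a median of −0.87 (0 of 15 past the test, limma camera, adjusted p = 0.00952, and adjusted p = 0.455 with an estimated correlation), and 0.0936 without BALB-RAG PBS replicate 3. The clock had −0.76 (4 of 16 down and 1 up, 6 and 1 adjusted over the list alone, 0.0351, and adjusted p = 0.0988 with an estimated correlation), 0.0838 without BALB/c OVA replicate 1, and 0.0539 with the block. Eicosanoid metabolism had 0.44 (2 of 8 up, 2 adjusted over the list alone, 0.0372, and adjusted p = 0.0988 with an estimated correlation), 0.0714 without BALB-RAG PBS replicate 3, and 0.13 with the block. NK cells had 0.91 (1 of 10 up, 1 adjusted over the list alone, 0.0388, and adjusted p = 0.443 with an estimated correlation), 0.141 without BALB/c OVA replicate 4, and 0.0933 with the block. In BALB/c the NK list level rose with OVA in replicates 3 and 4 alone.

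Among the 637 genes, the differences with the largest estimates were those of Clca1 (11.08), Jchain (8.24, adjusted p = 0.0327 with limma and 0.0707 without BALB-RAG OVA replicate 4), Igha (7.55), Chil4 (7.20), Rnase2a (6.63), Ccl8 (6.07), Arg1 (5.97) and Cxcl9 (5.87). All but Chil4 had arrays under log2 4, so their sizes and order rest in part on values at background. With such values set to 4 they were 10.32 for Clca1, 6.79 for Jchain, 7.44 for Igha, 6.16 for Rnase2a, 6.11 for Ccl8, 4.44 for Arg1 and 4.64 for Cxcl9. In the other direction they were Cyp2e1 (−3.74), Pon1 (−3.49), Pdk4 (−3.40), Angptl4 (−3.32), Klf15 (−3.02), Bpifa1 (−2.99), Cebpd (−2.92) and Fam107a (−2.84).

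Other splits of the same arrays were counted for each comparison. Among splits that ignore the sets of replicates, a share under 0.05 called as many genes for OVA in BALB/c (1155 genes, 1 of 35 splits as large, highest other 220), OVA on arrays labelled BALB-RAG (12, 1 of 35, highest other 4) and the lines after OVA (1777, 1 of 35, highest other 6). Most of these splits mix the sets, which were treated as batches and add spread to the split groups. The 8 splits that part all 4 pairs are too few for a share under 0.05 (highest others 0, 4 and 0 in the same order), so with the sets kept apart chance was not excluded. The 12 genes are few: simulations without a change in that comparison called 0 to 2, and of the genes called with changes 16.6% were false. Those simulations held no shift between the sets of replicates, and the second value came with 200 genes changed. They therefore do not show how many of the 12 are false. The 8 arrays alone gave 6, and the sets of replicates 3 and 5. For the lines after PBS 2 of 35 splits gave 296 or more, so these splits do not exclude chance. The other one follows replicates 1 and 2 against 3 and 4 and gave 817, which points to a batch structure. The highest of the other splits that part all 4 pairs gave 1 gene, and the blocked count was 617. The lines after OVA, on other arrays, shared 83 higher and 71 lower genes with this comparison, against 17.3 and 17.5 for independent lists. The other way went 18 and 9. For the shared genes this argues against chance, though genes that move together are not independent. For the difference of responses 2 of 100 drawn splits gave 637 or more; the other one, with 1145, separates the same sets of replicates on arrays labelled BALB-RAG, and the blocked count was 1188. With exposures exchanged only within the sets, 1 of 100 drawn splits, the real one, gave as many (highest other 450). Both kinds of drawn split also remove the OVA response of each line. They therefore test for any response and do not decide whether chance made the responses differ.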

How the results depend on the processing

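The settings named as deposited labels, longest runs, values set to 4 and doubtful arrays were chosen only after the results were seen. Of the named genes, 12772 values under alternatives kept their side of the threshold, 212 passed it and 330 no longer did; for lists, deposited labels apart, these were 3465, 103 and 177. The sign turned for 0 values called in either fit, but for 46 uncalled values of genes and 64 of lists. Rag2 stayed within 1 SD in 95 values. Of the main results 265 values stayed within 1.5 times and 60 did not. Array number and signal near background limit what could be called. The cause of the changes below was not tested unless named.

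With the replicate block the counts of genes became 1808 (OVA in BALB/c), 43 (OVA on arrays labelled BALB-RAG), 1188 (difference of responses) and 617 (lines after PBS), and with the batch term 1874, 70, 1255 and 652; blocking keeps 1153 of 1155, 12 of 12, 637 of 637, 296 of 296 and 1774 of 1777 calls. Among lists the block ended 4 calls on arrays labelled BALB-RAG (clock 0.0731, alveolar 0.0572, B cell 0.0766, eicosanoid 0.0731) and 3 in the difference of responses. It added 1 call each on arrays labelled BALB-RAG (extracellular matrix 0.0468), in the difference (endoplasmic reticulum stress 0.0214) and between the lines after PBS (alveolar 0.0392). Replicates 3 and 4 alone gave 561, 5, 200, 52 and 710 (lines after OVA), and replicates 1 and 2 alone gave 3 on arrays labelled BALB-RAG. Each set holds fewer arrays by construction. In the other comparisons replicates 1 and 2 gave higher counts, so array number alone does not account for those of replicates 3 and 4. All probe sets gave 2782, 43, 1460, 781 and 4836, with more features tested. Array weights gave 1975, 29, 1150, 537 and 2993. The larger direction turned in some settings. The share of rises for OVA in BALB/c, 57.1%, was 49.3% with array weights and 47.8% with deposited labels. The share more positive in the difference, 54.8%, was 46.2% with the stricter filter, 49.9% with weights, 49.8% with the batch term and 44.7% with deposited labels. Between the lines the share higher ranged from 39.9 to 67.2% after PBS and from 38.2 to 55.4% after OVA. A 2-fold minimum gave 519 in BALB/c, 157 between the lines after PBS and 794 after OVA. The arrays compared alone gave 6 for OVA on arrays labelled BALB-RAG and 149 for the lines after PBS.

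On arrays labelled BALB-RAG the 12 genes also became 25 with the stricter filter, 21 with means of probe sets, 22 with centring (16 up, 6 down) and 27 with quantile normalisation (16 up, 11 down) and 21 with values under log2 4 set to 4 (15 up, 6 down), against 10 up and 2 down as reported; scaling moved the median of all genes by under 0.1. Labels as deposited gave 29 there and 2715 for the lines after OVA.

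Camera with an estimated correlation called 8 lists for OVA in BALB/c, 0 on arrays labelled BALB-RAG, 5 for the difference, 0 for the lines after PBS and 10 after OVA. With fry 2 were called on arrays labelled BALB-RAG (cell cycle 0.0272, complement 0.0232). Labels as deposited called 0 lists in all 5 comparisons, against 85 of 150 list tests after realignment; the lowest adjusted p there was 0.539, and 40 of the 85 had the other sign, as names without their values would give.

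Leaving out each array gave 806 to 1193 genes for OVA in BALB/c, 6 to 41 on arrays labelled BALB-RAG, 422 to 706 for the difference, 178 to 411 for the lines after PBS and 1363 to 1852 after OVA. For lists it gave 18 to 23, 6 to 13, 16 to 22, 11 to 17 and 21 to 22. The correlation of responses ranged from −0.148 to −0.051. Without the arrays labelled BALB-RAG after PBS the counts were 1171 for BALB/c and 1877 for the lines after OVA, and 1714 for the latter also without BALB-RAG OVA replicate 2. The 3 longest runs alone gave 1128, 12, 618, 284 and 1729.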

Other observations

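The test in this part was chosen only after the results were seen. Extracellular matrix genes differed between the lines after PBS without a call for the whole list: Fn1 (1.01 ± 0.15), Mmp2 (0.93 ± 0.14) and Col1a2 (1.16 ± 0.23) were higher on the arrays labelled BALB-RAG and Mmp3 lower (−2.58 ± 0.24; SE, n = 4 per group, limma). The clock list had 6 members higher and 4 lower after PBS with a median of 0.00 and no call (adjusted p = 0.705), since its arms moved apart. Rtkn2 of alveolar type I cells fell with OVA in BALB/c (−1.03 ± 0.16), and the prostaglandin receptor Ptger4 (1.48 ± 0.16) and Tbxas1, thromboxane synthase (1.74 ± 0.27), rose, while their lists were not called. Slc4a1, an erythroid transporter, read 10.99 on BALB-RAG PBS replicate 2.

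A hypothesis on the genes that part the lines on all arrays is that some were carried along with the disrupted Rag gene when the line was bred from another strain. Of the 75 genes, 74 had a place in the order of protein-coding genes in the RefSeq table of GRCm38.p6. Among tested genes within 300 neighbours on each side of Rag2, 6 of 141 (4.26%) parted the lines, against 68 of 7331 (0.93%) elsewhere (Fisher's exact test, 2-sided p = 0.00262). The 6 were Tmem87a and Mybpc3, higher on arrays labelled BALB-RAG, and Disp2, Snap23, Golm2 and Mal, lower. Mybpc3 is in the cardiac muscle list, which varied with heart content, and without that list the shares were 5 of 139 (3.6%) and 67 of 7318 (0.92%, Fisher's exact test, 2-sided p = 0.0108). Tmem87a and Disp2 had been seen before the test, which weakens it. With labels as deposited the shares were 0.85% and 0.94% (Fisher's exact test, p = 1). A gene may differ in this way through its level or through a strain variant under its probes, which these arrays cannot separate.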
